A study of Escherichia coli with 4 samples.

How the data were processed

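The series holds 4 single-colour Agilent arrays of a custom *E. coli* gene expression design, with 2 unfed controls and 2 arrays titled spermidine-fed. Groups and replicate numbers came from the sample titles. Per the labels' protocols, 500 ng of total RNA was reverse transcribed with an oligo-dT primer that carried a T7 promoter, amplified to cRNA and labelled with Cy3. Bacterial messenger RNA carries only short and sparse poly(A) tails, so this priming may favour some transcripts, and values describe labelled RNA. All 4 arrays lay on a single slide, with the unfed arrays in one row and the spermidine-fed arrays in the next, so that row and group cannot be told apart. No optical density, cell count or parent strain is given in the sources used here.

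The scanner files hold background-corrected spot intensity (the processed signal) together with mean and background intensity, made by the authors with Agilent Feature Extraction 11.5.1.1 per the file headers, which the submitters' processing notes also name. These values were not normalized between arrays. The authors' deposited value table holds 5282 rows on what appears to be a log2 scale, with column medians of 6.42, 6.42, 6.41 and 6.40. Its scaling method and row summary are not given in the sources used here. Over 4337 rows matched to genes, each column had a rank correlation of 0.994 to 0.996 (Pearson 0.928 to 0.971) across genes with its own array's log2 signal, and its fed minus unfed change correlated with that of the scanner values at r = 0.934 across genes, with a slope of 1.19 and the same sign in 93.4%. It was used only as an alternative, and the log base was not settled beyond this match.

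From the scanner files, log2 of the processed signal minus each array's 75th percentile over non-control spots was computed. Control spots and spots flagged as outliers (5, 8, 1 and 0 per array) were left out, repeat spots of a probe were averaged, and probes had to be well above background on at least 2 of 4 arrays. A gene was the mean of its kept probes, usually 3. Genes were keyed by the locus tag in the files, and 4340 of 4347 tags matched a symbol in the RefSeq table of the MG1655 assembly ASM584v2, used for names and coding lengths only. Intergenic probes were analysed apart from genes. Several genes of the lists had no usable probe or no match and are not analysed here.

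Spermidine-fed and unfed arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over 4342 genes, threshold 0.05), without a block. The prior added 4.45 degrees of freedom to the residual 2, and the median SE of a change was 0.03. The number of arrays, 2 per group, limits the precision. *yobI* was not well above background on the unfed arrays and only a bound of at least 1.11-fold higher applies, taking for each dim array the higher of the lowest signal well above background and the probe's own. Gene lists were tested with camera at a preset correlation of 0.01 over lists with at least 3 measured members, and with an estimated correlation and fry as alternatives. The rule for named genes took the 12 largest rises and the 12 largest falls among genes past the threshold with non-overlapping groups, up to 4 members with the largest change per list, and always *speG*, *soxS*, *mntH*, *mntP*, *mntS* and *sodA*.

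Alternatives were normexp background correction (offset 50), quantile and median scaling, no filter or a filter on all 4 arrays, the brightest probe per gene, the deposited table, the replicate number as a block, a variance trend with robust estimation, each replicate left out in turn and a 2-fold minimum. Chosen after seeing the data were scaling to 6 E1A positive-control probes, which Agilent designs carry for spiked-in RNA and which the labels do not mention, leaving out probes marked as cross-hybridising, and limma's treat against a 2-fold change.

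The procedure was tested on simulated data for this comparison, with 50 of 4342 genes changed at each of 4 sizes, on the unfed means of the real genes and their SDs shuffled between genes. It recovered 28.0% of 50 genes changed by a log2 of 0.1, 84.0% of those changed by 0.25, 98.0% at 0.5 and 100% at 1. In the real data 4017 of 4342 genes passed, a far larger share than was changed here. The Benjamini-Hochberg cut-off was therefore less strict there, and these recovery rates do not carry over to the real comparison. The procedure called 3 of 4142 unchanged genes. That count holds for independent noise of the size seen between arrays of a group. It does not cover differences between cultures or slide rows. In a second simulation, genes were drawn independently and 3 lists were shifted by a log2 of 0.5, with all other genes unchanged. Camera recovered 3 of 3 shifted lists and called 0 of the others. Without correlation between genes, this does not measure how often camera calls lists falsely in the real data.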

Results

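Gene expression was measured on 4 single-colour (Cy3) Agilent custom arrays for *Escherichia coli*, each hybridised with labelled RNA from a strain that lacks *speG*, the gene for the spermidine N-acetyltransferase that inactivates excess spermidine. Per the labels, cultures grew in Luria broth for 1.5 h at 37 °C and then for 2.5 h with or without 3.8 mM spermidine. The arrays fall into 2 groups of 2, the unfed controls and the arrays titled spermidine-fed. Each array carried 15208 non-control spots, of which 14268 belonged to genes and 940 to intergenic regions. Between 99.6% and 99.8% of these spots were well above background and 0 were saturated. The median signal was 93.0 and 85.2 on the unfed arrays and 99.4 and 67.8 on the spermidine-fed arrays, against a median of about 1 (0.994 to 1.03) at the negative controls. All changes below are log2 differences, spermidine-fed minus unfed, of signals scaled to each array's 75th percentile, with n = 2 arrays per group.

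The deleted gene was examined first. *speG* (b1584) was not well above background on any array, with median signals of 0.965 and 0.994 in the unfed and 0.906 and 0.980 in the spermidine-fed arrays, at the level of the negative controls. The genes *araA*, *araB*, *rhaA* and *rhaB* also stayed at that level on all 4 arrays, and these 5 were the only genes of 4347 with no usable probe. The labels of the array titled spermidine-fed 2 disagree with each other. Its title and the protocols speak of spermidine, whereas its source and description speak of 1 mM manganese. It was kept under its title. The manganese genes were therefore read on each array. The manganese importer gene *mntH* stood at -0.14 and -0.20 on the unfed arrays and at 0.52 and 0.45 on spermidine-fed arrays 1 and 2. The exporter gene *mntP* stood at -1.11 and -1.13 against -0.88 and -0.69, the small protein gene *mntS* at -0.14 and 0.00 against -0.49 and -0.40, and *sodA*, for manganese superoxide dismutase, at 0.34 and 0.30 against -0.35 and -0.34.

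The comparison of spermidine-fed with unfed cells asks which transcripts differ in cells under spermidine stress. A pair of genes of the multiple antibiotic resistance operon had the largest rises. *marB* (b1532) rose by 5.40 (42.3-fold, SE 0.03) and *marA* (b1531), an activator of drug resistance genes, by 4.96 (31.2-fold, SE 0.03). The largest falls were in genes for acid resistance. The genes for 2 periplasmic acid chaperones led, *hdeB* (b3509), which fell by 6.79 (111-fold, SE 0.04), and *hdeA* (b3510), which fell by 5.71 (52.3-fold, SE 0.03), although the 3 probes of *hdeA* ranged from -6.86 to -3.42. Of 4342 genes tested, 687 passed limma's test at an adjusted p of 0.05 with at least a 2-fold change, 561 of them higher and 126 lower, and 178 were at least 4-fold higher against 24 at least 4-fold lower.

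**Figure D1:**
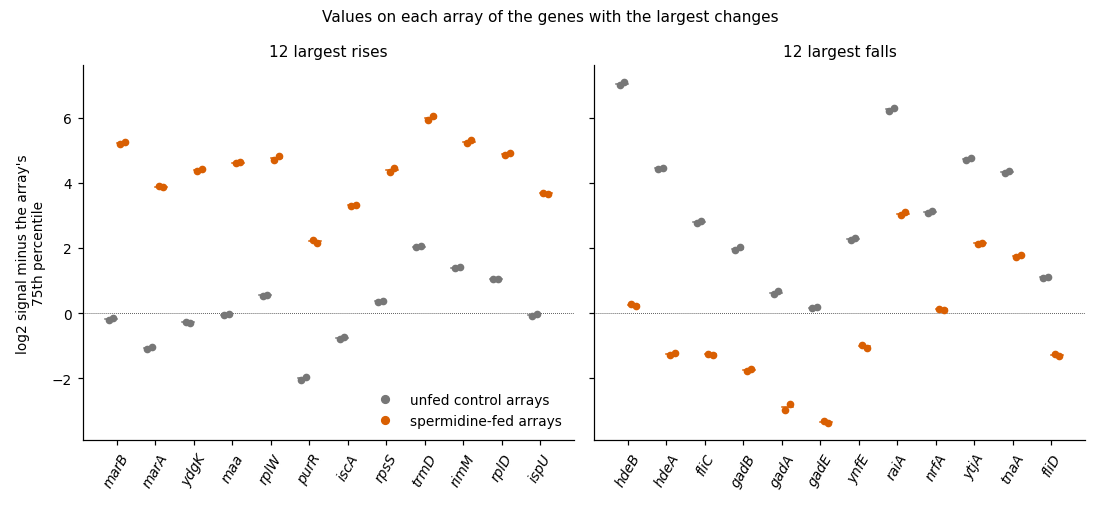
Scaled log2 signal (y axis, 0 is the array's 75th percentile) on each of the 4 arrays for the 12 genes with the largest rise and the 12 with the largest fall; each point is an array and each bar a group mean. The arrays of a group nearly coincide, while *marB* differs between groups by 5.40 and *hdeB* by -6.79.

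Without a minimum fold, 4017 genes passed, 1739 higher and 2278 lower, and 325 did not. The arrays of the 2 groups did not overlap in 4161 genes (95.8%, where chance gives 33.3%). The median absolute change was 0.47, far above the median SD between arrays of a group, 0.02 in both groups. No label says that the arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. Within a group, the median difference between arrays was 0.04 in the unfed and 0.05 in the spermidine-fed group, and repeat spots of a probe on a single array differed by as much, 0.04 to 0.05.

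Direction rests on the scaling. The array's E1A positive-control probes gave a second scale, chosen after seeing the data, that raised every change by 0.87. On that scale 4043 genes were higher and 144 lower, a higher share of 96.6% against 43.3%, and 1638 were at least 2-fold higher against 30 lower. With the array median as the scale every change moved up by 0.15, and 2073 genes were higher and 1887 lower (52.3% higher). With the authors' deposited value table, 610 genes were at least 2-fold higher and 505 lower (54.7% higher, against 81.7%), and with quantile normalization 469 and 207 (69.4%). Rises and falls below are therefore relative to the 75th percentile of the same array.

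Among the other genes with the largest rises, *ydgK* (b1626) rose by 4.67, *maa* (b0459), for maltose acetyltransferase, by 4.67 and *purR* (b1658), the repressor of purine synthesis, 18.4-fold. The tRNA methyltransferase gene *trmD* (b2607) and the ribosome maturation gene *rimM* (b2608) rose by 3.95 and 3.87, and *ispU* (b0174), for undecaprenyl diphosphate synthase, by 3.74. Among the other large falls, *fliC* (b1923), for flagellin, fell by 4.07, *ynfE* (b1587) fell 9.86-fold, and *raiA* (b2597), for a protein that binds idle ribosomes, 9.18-fold. *nrfA* (b4070), for nitrite reductase, fell 7.94-fold, *ytjA* (b4568) 5.97-fold and *tnaA* (b3708), for tryptophanase, 5.95-fold. SEs of these genes were 0.02 to 0.04, and the highest of their limma adjusted p-values was 3.1e-09.

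**Figure D2:**
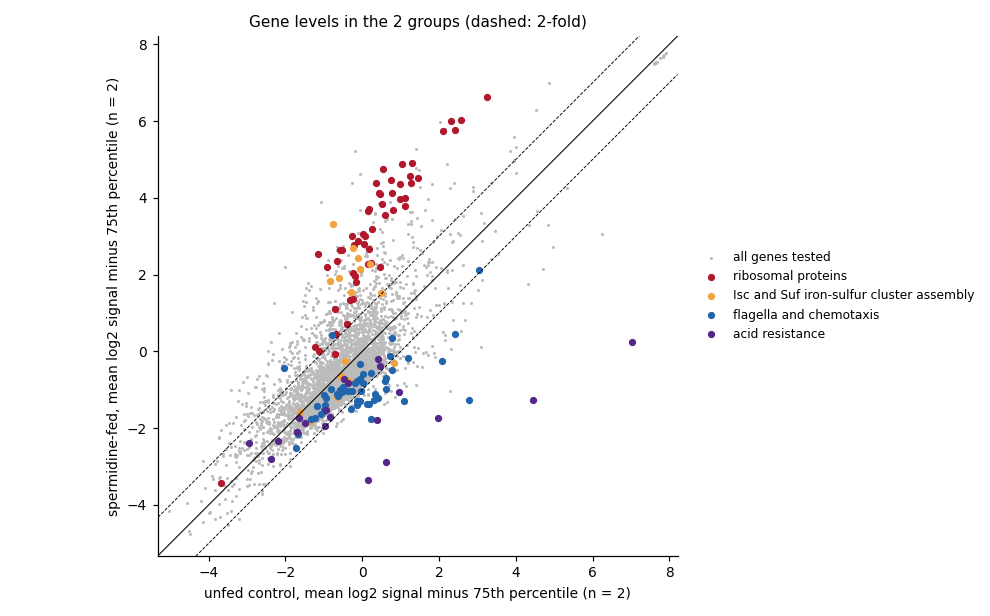
Mean scaled log2 signal of each of the 4342 genes in unfed (x axis) and spermidine-fed cells (y axis), 2 arrays per group, with 4 gene lists in colour, a solid line of equality and dashed lines at a 2-fold change. Ribosomal protein genes lie above the line, with a median change of 3.0, and most acid resistance and flagellar genes below it, with medians of -0.73 and -0.68 that become 0.14 and 0.19 with spike-in scaling.

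The 35 gene lists, fixed before the data were examined, were compared with the remaining genes by camera with a preset correlation of 0.01. It called 14 lists, 7 up and 7 down. With the correlation estimated from the data it called 0 lists, 1 at an unadjusted p under 0.05. That option rests on only the 2 residual degrees of freedom, so few lists could pass. Translation factors, with an estimated correlation of -0.068, below the preset, went from a camera p of 1.2e-05 to 0.044. The loss of calls therefore cannot be put down to correlation alone. Among the 14 called lists the estimate ran from -0.117 (histidine biosynthesis) to 0.730 (ribosomal proteins), with 0.264 for acid resistance. Where the estimate lies above the preset, as for ribosomal proteins, the camera p-value with the preset may be too small. Fry, which tests a shift in 1 direction without comparing lists with other genes, called 32. Member counts adjusted over the list alone were the same as those over all genes in every list but multidrug efflux (9 rose and 14 fell, in place of 13).

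Genes of the translation machinery rose most broadly. All 53 measured ribosomal protein genes rose, 51 of them at least 2-fold, with a median change of 3.0 (camera adjusted p = 8.3e-17; adjusted p = 0.603 with an estimated correlation). *rplW* (b3318) rose 18.6-fold, *rpsS* (b3316) 16.3-fold, *rplD* (b3319) 14.4-fold and *rplB* (b3317) 13.2-fold. Of 13 translation factor genes 12 rose and 1 did not pass (median 1.65, camera adjusted p = 8.6e-05; adjusted p = 0.539 with an estimated correlation). *lepA* rose by 3.16, *infA*, for initiation factor IF1, by 2.94, *fusA*, for elongation factor G, by 2.54 and *tsf* by 2.47. Of 12 cold shock genes 8 rose and 1 fell (median 0.57, camera adjusted p = 0.029; adjusted p = 0.726 with an estimated correlation). They include *infA* again, the RNA helicase gene *deaD* (2.02), *cspG* (1.08) and the ribosome binding factor gene *rbfA* (1.05). The call was lost with the brightest probe per gene (adjusted p = 0.059).

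The iron-sulfur cluster genes split by operon. Of 16 genes 10 rose and 5 fell (median 1.43, camera adjusted p = 0.042; adjusted p = 0.539 with an estimated correlation). The 8 genes of the *isc* operon, the housekeeping assembly system, rose by 1.84 to 4.07, led by *iscA* (b2528, 16.8-fold), *iscX* (7.57-fold), *iscU* (6.46-fold) and *hscA* (5.84-fold). The 5 that fell belong to the *suf* operon, the assembly system used under iron limitation and oxidative stress, from *sufA* (-1.15, and -0.27 with spike-in scaling) and *sufB* (-0.54, or 0.33 with spike-in scaling) to *sufS* (-0.07, or 0.80). The *suf* genes were named after their values were seen. The list lost its call with median scaling (adjusted p = 0.065) and with the brightest probe per gene (adjusted p = 0.054).

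Energy and amino acid genes supplied the remaining calls upward. Of 9 ATP synthase genes 7 rose and 1 fell (median 0.71, camera adjusted p = 0.025; adjusted p = 0.561 with an estimated correlation), led by *atpI* (1.79) and *atpA* (1.49). Of 23 NADH dehydrogenase and oxidase genes 16 rose and 6 fell (median 0.31, camera adjusted p = 0.042; adjusted p = 0.539 with an estimated correlation). *nuoA* rose by 0.94 and *nuoI* by 0.78, and *cydB* changed by -0.86, or 0.01 with spike-in scaling. *nuoC* changed by 0.78, a sign that turned with quantile normalization (-0.17) and in the deposited table (-0.21). The call on this list was lost in 8 of 15 alternatives, where its adjusted p reached 0.566. The ATP synthase call was lost in 3 of them. Its median became 0.23 with quantile normalization (camera adjusted p = 0.226) and 0.34 in the deposited table (camera adjusted p = 0.234). All 8 histidine biosynthesis genes rose (median 0.54, camera adjusted p = 0.013; adjusted p = 0.539 with an estimated correlation), with *hisG* at 1.50, *hisB* at 1.29 and *hisC* at 1.27. This call was lost with spike-in scaling (adjusted p = 0.112).

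The general stress genes controlled by RpoS all fell, 31 of 31, with a median of -0.85 that became 0.02 with spike-in scaling (camera adjusted p = 7.2e-06; adjusted p = 0.539 with an estimated correlation). *yeaG* fell 4.16-fold, *wrbA* 4.12-fold, *osmY* 3.78-fold and *talA* 2.29-fold. Of 20 acid resistance genes 19 fell and 1, *cadC* (0.57, named after its value was seen), rose, with a median of -0.73, or 0.14 with spike-in scaling (camera adjusted p = 5.3e-04; adjusted p = 0.603 with an estimated correlation). *gadE* (b3512), the activator of the glutamate-dependent system, fell 11.4-fold. The glutamate decarboxylase genes *gadB* (-3.72) and *gadA* (-3.52) are near-identical copies whose probes are all marked as cross-hybridising in the array design, so their separate values are uncertain.

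Of 53 flagellar and chemotaxis genes 51 fell, 20 of them at least 2-fold, with a median of -0.68, or 0.19 with spike-in scaling (camera adjusted p = 1.1e-07; adjusted p = 0.539 with an estimated correlation). *fliC* fell 16.7-fold, *fliD*, for the filament cap, 5.23-fold, *fliT* 5.03-fold and *fliS* 4.01-fold. The 2 members that rose, named after their values were seen, were *flhD* (1.60) and *flhC* (1.22), which encode the master activator of the flagellar genes.

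Of 40 genes for anaerobic respiration and fermentation 35 fell and 3 rose, with a median of -0.68, or 0.19 with spike-in scaling (camera adjusted p = 3.5e-05; adjusted p = 0.539 with an estimated correlation). *nrfA* fell 7.94-fold, *dmsB* and *dmsA*, for dimethyl sulfoxide reductase, 4.07-fold and 3.22-fold, and *fumB*, whose probes are marked as cross-hybridising, 3.45-fold. Of 43 measured sugar uptake genes 30 fell and 6 rose, with a median of -0.49, or 0.39 with spike-in scaling (camera adjusted p = 0.013; adjusted p = 0.619 with an estimated correlation). The galactitol genes *gatC* and *gatB* fell 2.95-fold and 2.94-fold, whereas the trehalose genes *treB* and *treC* rose by 2.64 and 1.68. Of 35 methionine and cysteine genes 30 fell and 4 rose, with a median of -0.46, or 0.41 with spike-in scaling (camera adjusted p = 2.9e-03; adjusted p = 0.539 with an estimated correlation). *cysI* changed by -0.81, *metC* by -0.70 and *cysD* by -0.67, all above 0 with spike-in scaling, and *cysK* rose by 0.69. Of 43 iron uptake genes 33 fell and 8 rose, with a median of -0.35, or 0.53 with spike-in scaling (camera adjusted p = 0.029; adjusted p = 0.676 with an estimated correlation). Its largest changes were rises of *fhuF* (0.93), *exbD* (0.74) and *fhuA* (0.62), beside *fhuD* (-0.70, or 0.18 with spike-in scaling). This call was lost with quantile normalization (adjusted p = 0.076), in the deposited table (0.057) and with spike-in scaling (0.145).

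**Figure D3:**
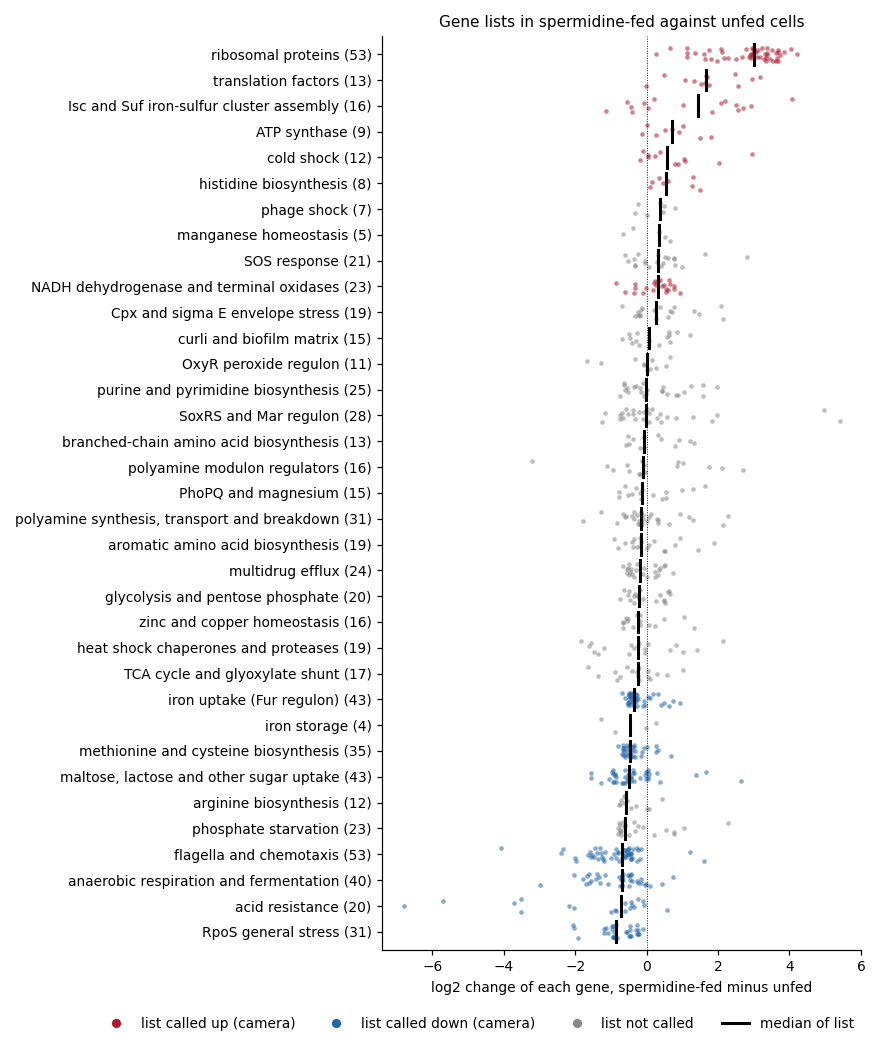
Log2 change of each measured gene (points, x axis) in the 35 gene lists (rows, with the number of genes measured), ordered by list median (black bars); colours mark the lists called up or down by camera with the preset correlation. Medians run from -0.85 for RpoS genes, or 0.02 with spike-in scaling, to 3.0 for ribosomal proteins, and single genes depart far from the median in lists that were not called, such as SoxRS and Mar.

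The 21 lists that were not called had camera adjusted p-values of 0.120 to 0.942, and 5 of them held members at least 2-fold higher and members at least 2-fold lower. In the list for polyamine synthesis, transport and breakdown 11 genes rose and 19 fell (median -0.15). The spermidine exporter genes *mdtJ* (b1600) and *mdtI* (b1599) rose 4.90-fold and 4.40-fold, and *puuR*, the repressor of putrescine breakdown, rose by 1.31. The lysine decarboxylase gene *cadA* fell by 1.78. Among 16 genes for regulators and other proteins whose synthesis polyamines are known to influence, 6 rose and 9 fell. They include *fis* at 2.71, *rpoZ* at 2.11, *uvrY* at 1.75 and *raiA* at -3.20. In the SoxRS and Mar list 13 rose and 13 fell. Beside *marA* and *marB*, the flavodoxin gene *fldA* rose by 1.84 and the repressor gene *marR* by 1.97, with probes from 1.07 to 3.66, while *soxS*, the superoxide response activator, fell by 1.24 (SE 0.02) and *sodA* changed by -0.67, or 0.21 with spike-in scaling. The mean change of this list, 0.37, and its median, -0.03, differ in sign. In the OxyR peroxide list 5 rose and 5 fell, with a mean of -0.16 although the direction from camera was up. The catalase gene *katG* fell 3.18-fold and *dps* 2.41-fold, *ahpF* rose by 0.64, and *ahpC* changed by 0.53 but by -0.55 with quantile normalization and -0.51 in the deposited table.

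In the manganese list 3 rose and 2 fell. *mntH* rose by 0.65 (SE 0.03), *mntR* by 0.52 and *mntP* by 0.33 (SE 0.06), *mntS* changed by -0.37, or 0.50 with spike-in scaling, and *sodA* as above. Of 16 zinc and copper genes 4 rose and 11 fell (median -0.23), with *znuA* at 1.32, *zinT* at 1.04, and *cusA* and *copA* at -0.67 each, or 0.20 with spike-in scaling. Of 4 iron storage genes 1 rose and 2 fell, with *ftnA* at -0.89 and *ftnB* at 0.26. Of 19 heat shock genes 5 rose and 11 fell (median -0.23). The protease gene *ftsH* rose by 2.13, and the chaperone genes *groL*, *groS* and *ibpA* fell 3.61-fold, 3.06-fold and 2.95-fold. Of 19 envelope stress genes of the Cpx and sigma E systems 11 rose and 8 fell (median 0.26), with *cpxP* at 2.13, *bamA* at 2.08, *skp* at 1.45 and *bamB* at 1.33. Of 7 phage shock genes 4 rose and 2 fell, *pspE* most (0.80). Of 21 SOS genes 13 rose and 6 fell (median 0.32), with *dinG* at 2.80, the division inhibitor gene *sulA* at 1.63, *recA* at 0.99 and *uvrB* at 0.79.

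Of 17 TCA cycle and glyoxylate genes 4 rose and 11 fell, with *aceB* at -1.64, *aceA* at -1.36 and *sdhC* at 1.03. The median of this list, -0.23, became -0.68 with quantile normalization and -0.92 in the deposited table, where camera called it down (adjusted p = 3.7e-03 and 2.2e-03). Of 20 glycolysis and pentose phosphate genes 8 rose and 12 fell, with *gnd* at 0.66, *pgl* at -0.74, or 0.13 with spike-in scaling, and *pgk* at 0.64, which became -0.37 with quantile normalization and -0.00240 in the deposited table. Of 12 arginine genes 1 rose and 9 fell (median -0.57), with *argC* at -0.76 and *carB* at -0.75, both above 0 with spike-in scaling. Of 13 branched-chain genes 6 rose and 7 fell, with *leuB* at 1.32 and *ilvM* at 1.22. Of 19 aromatic amino acid genes 8 rose and 10 fell, with *aroB* at 1.89, *aroK* at 1.42 and *mtr* at -0.90. Of 25 purine and pyrimidine genes 11 rose and 12 fell, with *purB* at 1.96, *pyrD* at 1.58 and *purA* at 1.57. Of 24 multidrug efflux genes 9 rose and 13 fell, with *mdtA* at 0.74 and *acrD* at -0.54, or 0.33 with spike-in scaling. Of 15 PhoPQ and magnesium genes 7 rose and 8 fell, with *mgrB* at 1.63, the magnesium channel gene *corA* at 1.30 and *phoQ* at 1.00. Of 23 phosphate starvation genes 6 rose and 17 fell (median -0.60), with *pstB* at 2.29 and *pstC* at 1.05. *phnH* was at -0.80 and *phnI* at -0.79, or 0.07 and 0.08 with spike-in scaling. Of 15 curli and biofilm genes 8 rose and 7 fell, with *pgaB* at 1.20, whose probes ranged from 0.34 to 2.32. In 6 further lists without a call the mean was above 0 and the median below it. They were polyamine synthesis and transport (0.03), the polyamine-influenced regulators and other proteins (0.15, median -0.11), branched-chain (0.20, median -0.08), aromatic (0.11, median -0.15), purine and pyrimidine (0.25) and PhoPQ genes (0.17, median -0.12). Medians of all 35 lists, called or not, were above 0 with spike-in scaling, against 12 with the 75th percentile.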

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

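The tests on replicate RNA and on manganese below were chosen only after the result was seen. Intergenic probes, outside the gene comparison, also changed between groups. Of 924 intergenic features tested with limma, 796 passed at an adjusted p of 0.05, 278 higher and 518 lower in spermidine-fed cells, and 77 were at least 2-fold higher and 29 at least 2-fold lower. These splits rest on the 75th percentile as the scale, and spike-in scaling raises every change by 0.87. Their changes had a rank correlation of 0.455 across features with that of the more strongly changed flanking gene.

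The E1A positive-control probes, also outside the gene comparison, were 0.84 lower in log2 on the spermidine-fed arrays, so that the 75th percentile of the genes stood 0.87 higher relative to them. Each array's percentile relative to these probes was -1.81 and -1.85 in the unfed and -0.95 and -0.97 in the spermidine-fed group. Among the 6 probes used, the shift ran from -0.58 at the dimmest to -0.93 at the brightest.

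By the median difference over all spots, the arrays of a group agreed about as closely as repeat spots. The ratio of the median difference between arrays to that between repeat spots on an array was 0.876 in the unfed and 1.06 in the spermidine-fed group. A candidate explanation is that both arrays of a group carried the same RNA, which predicts a ratio near 1 and would make the p-values describe technical spread. Among the brightest spots the ratio was 1.96 and 1.92. Different probes of a gene also weakly shared the difference between the arrays of a group. Their rank correlation across genes was 0.117 in the unfed and 0.137 in the spermidine-fed group, after an intensity trend was removed. Small differences beyond spot noise were thus present. The same RNA, labelled or hybridised apart, still cannot be told from separate cultures that varied very little. No biological explanation was tested.

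The manganese in the labels of spermidine-fed replicate 2 could mean that this array held manganese-grown cells, and manganese is known to repress *mntH* and *mntS* and to induce *mntP*. If this array alone had manganese in place of spermidine, it should differ from replicate 1 about as unfed arrays do, but the SD of the difference across genes was 0.0590 between these arrays and at least 0.896 between groups, which argues against that. From replicate 1 to 2 *mntP* differed by 0.19, the direction manganese would give, against -0.02 between the unfed arrays. *mntS* differed by 0.09, the opposite direction, but by 0.14 between the unfed arrays. *mntH* differed by -0.07, close to the -0.06 between the unfed arrays. If both arrays held manganese-grown cells in place of spermidine-fed ones, *mntH* should be lower than in unfed cells, and it was 0.65 higher, which argues against that. But *mntP* was 0.33 higher and *mntS* changed by -0.37 (0.50 with spike-in scaling), the directions manganese would give, so manganese beside spermidine, on this array or both, stays open, as does an error in the source and description fields.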

How the results depend on the processing

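The E1A scaling (spike-in), the removal of cross-hybridising probes and treat were chosen after seeing the data. Of 4017 changed genes, 687 remained with a 2-fold minimum and 611 passed treat. The other settings gave 3202 (normexp) to 4187 (spike-in). The replicate number as a block gave 4053. The titles' numbers are not said to mark shared cultures, and the deviations of same-numbered arrays correlated at 0.290 across genes; the replicate block changed no list's call. The 561 genes at least 2-fold higher became 346 with normexp and 1638 with spike-in scaling. The 126 lower became 66 with normexp, 207 with quantile normalization, 505 in the deposited table and 30 with spike-in scaling, which also turned 1739 higher and 2278 lower into 4043 and 144. Of the 687 genes, normexp kept 412, quantile normalization kept 580 and the deposited values kept 581, all in the same direction. Spike-in scaling kept 591, and its shared shift of 0.87 could not reverse any gene changed at least 2-fold. Leaving out each array in turn gave 3908 to 4025 genes and 13 or 14 lists.

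Against 14 lists, estimated correlation gave 0 and fry 32. Spike-in scaling turned the medians of RpoS (0.019), acid resistance (0.14), flagella (0.19), anaerobic (0.19), sugar uptake (0.39), methionine and cysteine (0.41) and iron uptake (0.53) above 0 by construction, since it adds the same amount to every gene. Camera called the first 6 down on that scale too. It compares a list with the other genes, so a shared shift cannot turn its direction, and these calls are no separate support. For 149 named genes, 2199 of 2232 values kept direction and side of the threshold, 5 lost the call and 28 reversed. Most of these genes were picked for large changes in these same data. The replicate block and the variance trend leave the log2 change as it was, and the probe filters alter few genes. Many of these values could therefore hardly differ, and the tally is a weak test. Reversed with quantile normalization were *ahpC* (-0.55), *nuoC* (-0.17) and *pgk* (-0.37), and in the deposited table *ahpC* (-0.51), *nuoC* (-0.21) and *pgk* (-0.00240); the cause was not tested. Reversed with spike-in scaling were *fhuD* (0.18), *sodA* (0.21), *mntS* (0.50), *cusA* (0.20), *copA* (0.20), *bcsZ* (0.17), *cydB* (0.013), *pgl* (0.13), *rpe* (0.24), *argC* (0.11), *carB* (0.13), *argB* (0.16), *argH* (0.24), *cysI* (0.060), *metC* (0.18), *cysD* (0.20), *mdtL* (0.22), *acrF* (0.32), *acrD* (0.33), *pagP* (0.11), *phnH* (0.070) and *phnI* (0.082). Over 99% of spots were well above background; 4339 of 4342 genes kept a probe above background on all 4 arrays.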

Other observations

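The groups in the next 2 paragraphs were picked after their values were seen, and their tests were not corrected for that choice. All 11 genes for O-antigen and its rhamnose rose by 1.63 to 2.66, led by *rfbX* (6.32-fold) and *rfbD* (6.04-fold). Of 14 genes for the lipopolysaccharide core 12 rose and 2 fell (median 1.44), with *waaO* at 2.15, and with both that fell, *waaC* (-0.40) and *waaA* (-0.21), above 0 with spike-in scaling. Of 17 genes for fatty acid and phospholipid synthesis 16 rose and 1, *accC* (-0.06, or 0.81 with spike-in scaling), fell (median 1.30), with the phosphate acyltransferase gene *plsX* up 9.65-fold and *fabD* up 5.84-fold.

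The 3 genes of the tryptophanase operon fell, *tnaC* 3.51-fold, *tnaA* 5.95-fold and *tnaB* 4.77-fold. In the operon of *ynfE*, 4 of 5 genes fell, among them *ynfH* (-0.81, or 0.06 with spike-in scaling), with *ynfG* 4.01-fold and *ynfF* 3.82-fold lower, and *dmsD* was at 0.02 (limma adjusted p = 0.615). All 5 glycogen genes fell, *glgC* 2.58-fold and *glgA* 2.29-fold, while *glgP* (-0.59) and *glgX* (-0.73) were above 0 with spike-in scaling. The small RNAs that bind the regulator CsrA, *csrB* and *csrC*, fell 2.11-fold and 2.49-fold. None of 12 ribosomal RNA genes, whose near-identical copies share signal, passed, with changes of -0.16 to -0.11, all above 0 with spike-in scaling.

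The opposite course of ribosomal protein and stress genes was weighed, a difference of 3.86 between the medians of the ribosomal protein and RpoS lists, with the test on scaling chosen after the result was seen. With normexp, quantile normalization or the deposited table they differed by at least 2.97, and after a correction for probe GC content and gene length, fitted on 4231 other genes, by 3.63, so these tests argue against either as the whole cause. A candidate explanation is that fed cultures were at a different growth stage at harvest. It predicts rapid-growth genes above 0 and stationary-phase genes below 0. The median of 6 rapid-growth genes (1.11, all higher) exceeded that of 5 stationary-phase genes (-0.23, 4 lower) by 1.34. Spike-in scaling keeps this difference but moves the medians to 1.98 and 0.64, so the stationary-phase part fails on that scale. Moreover, *hpf* was higher (0.35) and 3 of the 5 stationary-phase genes were already in the lists. Of the rapid-growth genes, *rpoB*, *rpoC*, *nusG* and *nusA* lie beside or near ribosomal protein or translation factor genes of the lists. They are therefore not an independent sign of growth stage. Without an optical density or cell count per culture, growth stage and a direct effect of spermidine cannot be told apart.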
